A study of Lycium chinense and Mus musculus with 2 samples.

How the data were processed

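The labels describe non-coding RNA profiling of 1 fruit sample and 1 sample of mouse blood, made from total RNA extracted with Trizol and an Illumina TruSeq RNA kit, per the labels' protocols. Bowtie2, SAMtools, HOMER and FastQC 0.11.5 are named in the submitters' processing notes, with no role for each. The peak caller, its control library, the pooling of samples, the genome build and the gene annotation are not given in the sources used here. The table used is 1 list of peaks presented as mouse blood and attached to the series, not to a sample. No column or peak name matches a label of either sample, so its values were treated as belonging to no group. Values of the fruit sample were not analysed here, and the number of columns of other samples left aside was 0.

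Each row of the deposited table gives a peak summit and, where it overlaps a gene, 1 such gene. The 1327 rows held 1123 summits in 889 regions. Region numbers ran without gaps, and the rows per summit matched the deposited count of overlapped genes. The deposited peak score equals the whole part of 10 times the −log10 q value in all 1327 rows. The fold enrichment is the authors' ratio over a background that the deposited table does not name, and ranged from 1.33 to 40.4 over regions with a median of 5.55. The deposited −log10 q values are per summit, and the smallest of a region was 1.31. The −log10 p values were not used here. No read counts are in the table and all peaks are without strand, so the depth is unknown, a single fold enrichment has no interval, and overlapping or antisense genes are not separated. A list of called peaks holds no values for regions below the threshold. Coordinates are as in the table, and whether its starts count from 0 or 1 is not stated.

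Summits were merged by region name, and each region took its highest-scoring summit. A region's class was taken from the table's annotation at the region's centre, in the order 3′ UTR, 5′ UTR, exon, intron, outside the gene body. Shares carry exact (Clopper-Pearson) 95% intervals, and shares among the 445 regions with the highest scores and the other 444 were compared with Fisher's exact test. This comparison, the groups by symbol, the GO test and the pseudogene test were chosen after the table was seen. A microRNA region was one whose closest transcription start in the table is a microRNA gene within 100 bases. The 14 lists of genes were fixed before the data were examined, together with the planned tests and alternatives. They hold mouse symbols and were matched through human symbols assigned by hand, leaving out members with no clear human counterpart. A percentile among 10000 random lists was planned for lists with 3 or more overlapped members, and no list had that many. The genes named were the 15 with the highest score, the 3 highest in each class that holds at least 1% of regions, and the members of the lists. Other genes are marked as chosen later. A result that this rule takes in is not reported here.

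The planned designs assumed that the table held values of the blood sample, to which it could not be tied. GO terms of at least 10 genes were tested with Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Results for all overlapped genes and for exonic overlaps had both been seen when the former was taken as the main one. On simulated data with the same 777 genes and 20 terms planted at 3 times the share, the test called 20 planted terms and 0 of 180 others. Simulated memberships were drawn independently, and the planted ratio was above that of every term called in the main test. The simulation therefore does not measure power or error for the real terms. Pseudogenes were recognised by a symbol of the form parent, P, number, where the parent's symbol is a protein-coding gene in the mouse annotation GENCODE M21 and the full symbol is not. That annotation was used only for symbols and for the ends of the mouse chromosomes, since its coordinates are of another species than the table's. Comparisons of the fruit with the blood, planned before the data were examined, could not be made. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.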

Results

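The series describes 2 samples with 1 sample in each group: fruit of Lycium chinense (goji, a plant of the nightshade family), and blood of C57 BL/6J mice given Lycium chinense into the stomach at 10 mL/kg, drawn after 14 days. The question was whether plant microRNAs, short RNAs that silence matching transcripts, pass from the gut into mouse blood. The table analysed here is presented as peaks of mouse blood, but its content does not match that description. All 1327 rows carried a human Ensembl gene identifier and 0 carried a mouse one. Of the 889 regions, 31 lay on chromosomes or contigs that the mouse genome GRCm38 lacks and a further 111 ended past the last annotated base of the mouse chromosome of the same name. The peak names carried a tag with the letters IP that appears in 0 of the 15 label fields examined. The regions could therefore be tied to neither sample, and the values below describe 1 human-annotated list of enriched regions of unstated origin. No control animal, fruit value or read count was analysed here, so the depth is unknown and no comparison between conditions was made.

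The table held no plant microRNA and few microRNA loci. Among 1672 gene symbols named anywhere in it, 0 belonged to the 41 plant microRNA families searched. Because the annotation is that of a human genome, it could not name a plant sequence, and this 0 does not bear on whether plant microRNA was in the blood. For 1 of 889 regions the closest transcription start was that of a microRNA within 100 bases: MIR1282, at chromosome 15 from 43793732 to 43793953 in the coordinates of the table, whose build is not given in the sources used here, with a fold enrichment of 4.41 and a −log10 q of 91.8. That region also lay over intron 2 of SERF2 at its centre. A second region, of 6.62-fold enrichment, overlapped MIR3610 and the 5′ UTR of RAD21. MIR15B, a member of the miR-15/16 family, was the closest start to a region 155 bases away, but that region of 14.0-fold enrichment was centred in exon 5 of its host gene SMC4, a condensin subunit. Within 1000 bases of a microRNA start there were 7 regions, 4 of them centred in exons of SMC4, RPL10A and YY1.

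Most regions lay in exons or UTRs of annotated genes. The centre fell in an exon or UTR for 742 of 889 regions, or 83.5% (exact 95% binomial interval 80.9 to 85.8, which covers counting error only, since neighbouring regions of 1 gene are not independent). Exons other than UTRs held 590 regions, 3′ UTRs 130 and 5′ UTRs 22. A further 73 regions were centred in introns and 6 lay just outside the body of a gene they touched. The other 68 had no overlapped gene in the deposited annotation, which does not place them outside genes. An example, of 21.2-fold enrichment, lay 3693 bases past the RPL6 start, while a region in RPL6 exon 2 lay at 1114. In 133 regions the centre was exonic while both ends reached into the flanking introns. In a comparison chosen after the data were seen, the 445 regions with the highest scores were centred in 3′ UTRs less often than the other 444, 9.44% against 19.8% (Fisher's exact test over regions, two-sided, Benjamini-Hochberg adjusted over 6 classes, p = 6.8e-05). They were centred in exons more often, 73.0% against 59.7% (Fisher's exact test, adjusted p = 8.2e-05), and in introns less often, 5.84% against 10.6% (adjusted p = 0.021), although introns held 7.87% of the 89 regions with the highest scores, close to their share of all regions, 8.21%. By the same Fisher's exact test, the shares of 5′ UTRs (2.92% against 2.03%, adjusted p = 0.78), gene-adjacent regions (0.899% against 0.45%, adjusted p = 0.82) and regions without a gene (7.87% against 7.43%, adjusted p = 0.90) did not pass the threshold. These tests took regions of 1 gene as independent, so their p-values may be too small. Exon regions with high scores included pseudogenes and clone-named genes, such as RPL39P3, RPL10AP6, RPS6P25 and AC007688.1, each annotated as a last exon with no UTR. The comparison was not repeated without such genes. It therefore does not show that position within a transcript goes with the score. Where genes overlap, the exonic annotation was taken first, and taking the intronic one first lowered the exon and UTR share to 72.7% and raised the intron share from 8.21% to 19.0%. Weighting regions by score gave 3′ UTRs 8.02% in place of 14.6%.

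**Figure D1:**
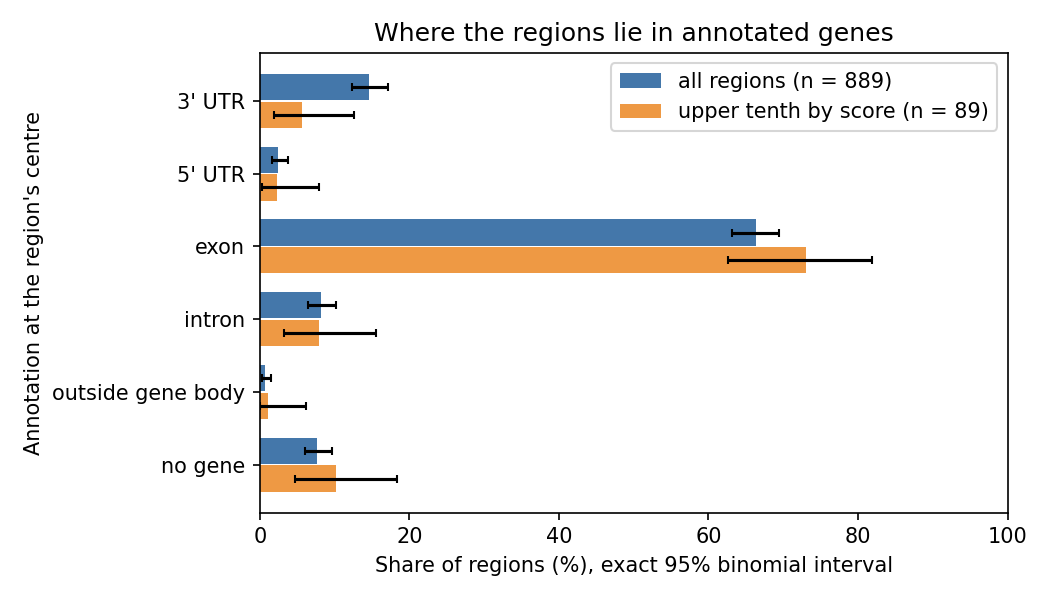
Share of regions (%) by the annotation at the region's centre, for all 889 regions and for the 89 with the highest scores, with exact 95% binomial intervals as bars. Exons hold 66.4% of all regions and 73.0% of those 89, and 3′ UTRs hold 14.6% and 5.62%. Exon regions include those of pseudogenes such as RPL39P3.

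Fold enrichments and q values are those the authors' peak list gives for each region's highest-scoring summit, without replicates or errors. The highest score belonged to HIST1H4C (ENSG00000197061), a replication-dependent histone H4 gene, at chromosome 6 from 26103963 to 26104317, with 6.29-fold enrichment and a −log10 q of 323. RPS6 (ENSG00000137154), a protein of the small ribosomal subunit, had 4 regions in exons 2 to 5, the strongest with 8.59-fold enrichment in exon 5. RPL35A and RPL10A, proteins of the large ribosomal subunit, reached 7.32-fold in exon 3 and 17.2-fold in exon 4. Among the 15 highest-scoring genes there were also the pseudogenes RPL39P3 at 4.39-fold, RPL10AP6 at 6.38-fold, RPS6P25 at 11-fold and MTATP6P1 at 4.92-fold. The clone-named genes AC007688.1 (22.2-fold), AC010343.1 (5.78-fold), AC246787.1 (8.41-fold), AL009174.1 (9.36-fold) and AC004453.1 (2.63-fold), and HIST2H2AB, a histone H2A gene (4.09-fold), were also among them. Regions of pseudogenes and of overlapping genes are uncertain as to the gene, since peaks carry no strand and near-identical copies may share reads.

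**Figure D2:**
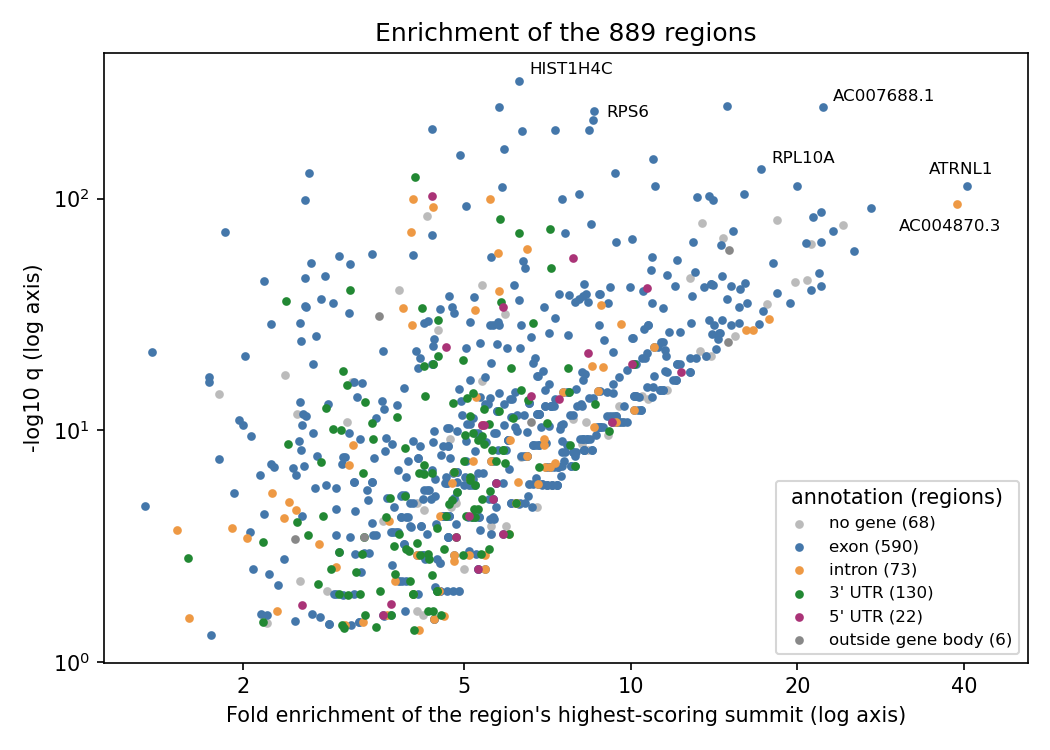
Fold enrichment (log axis) against −log10 q (log axis) of the highest-scoring summit of each of the 889 regions, as the authors' list gives them, coloured by annotation. HIST1H4C has the highest −log10 q (323) at 6.29-fold, and ATRNL1 the highest fold (40.4) at a −log10 q of 113.

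Within the other annotation classes, the highest-scoring 3′ UTR regions after HIST2H2AB were in HIST1H1D, a linker histone gene (5.80-fold), and SNRPD2, a core spliceosomal protein (7.15-fold). The 5′ UTR regions were led by HIST1H1E, another linker histone gene (4.38-fold), ID2, an inhibitor of helix-loop-helix transcription factors (7.88-fold), and CCDC50 (10.7-fold). Among regions annotated as intronic, TMPRSS11GP had 4.05-fold, FP671120.1 5.58-fold and AC004870.3 38.9-fold enrichment. The closest start to the FP671120.1 region was that of the ribosomal RNA gene RNA5-8SN2, 2165 bases away. Whether that region lies in ribosomal RNA sequence was not tested. The highest-scoring regions with no overlapped gene in the annotation were nearest to AP000431.1 (4.29-fold), PDE4B (18.4-fold) and RPL5 (13.5-fold).

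Groups of genes were chosen by symbol after the table had been seen. Each gene was given its highest fold, which favours genes with more regions, and the median over all regions was 5.55. The 12 ribosomal protein genes with a region had a median highest fold of 7.46 (range 3.42 to 17.2), and the 21 ribosomal protein pseudogenes one of 4.39 (1.74 to 14.6). Of the former, RPL23A (8.23-fold) was overlapped at the region's centre only in intron 2. That region also overlapped SNORD4A and was classed by the last exon of AC010761.1. The 18 histone genes, which encode H1, H2A, H2B, H3 and H4 proteins, had a median of 2.94 (1.74 to 7.92). The 7 translation initiation factor genes, EIF4G2 and EIF3H among them, had 20 regions and a median of 5.24 (3.43 to 16.0). The 5 mitochondrial ribosomal protein genes had a median of 5.04 (3.42 to 27.1), with MRPL22 the highest. The 3 mitochondrially encoded genes MT-CO2, MT-CO3 and MT-ND1 stood at 1.86, 1.37 and 1.33-fold. The ranges of the ribosomal protein, pseudogene, histone and initiation factor groups overlapped, and no difference between groups was tested.

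Of the 569 gene symbols overlapped, 407 had 1 region, 162 had 2 or more and 34 had 5 or more. The genes named here were chosen after their values were seen. RAD21, the cleavable subunit of the cohesin ring, had the most, with 11 regions over its exons and UTRs and up to 22-fold enrichment. SUZ12, a core subunit of the Polycomb repressive complex that methylates histone H3, had 9 regions with up to 18.1-fold. CCDC50 and SMC4 also had 9 each, and AC079594.2, in whose intron the SMC4 regions lie, was counted with the same 9. MALAT1, an abundant nuclear long non-coding RNA, had 9 regions, but at 2.60-fold or less. PCM1, a centriolar satellite protein, and SPATS2 had 8 each. EZH2, the catalytic partner of SUZ12, had 2 regions with up to 7.95-fold. ATRNL1 had 3 regions in exons 22 to 24, with 25.3, 10.2 and 40.4-fold enrichment in that order. GPRIN3 was covered by 4 regions with 39 summits at chromosome 4, the longest running for 4625 bases from 89245011 to 89249636.

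The lists of blood, tissue and small RNA genes fixed before the data were examined were nearly empty. Of 187 members with a human symbol, 2 overlapped a region. These were MALAT1, from the list of abundant non-coding RNAs, and CSF1R, the macrophage colony-stimulating factor receptor from the monocyte list. The CSF1R region, of 2.91-fold enrichment, lay in intron 1 together with the pseudogene RPL7P1, and no CSF1R exon was covered. None of the 17 erythrocyte genes (which include the globins HBA1, HBA2 and HBB), 10 neutrophil, 14 B cell, 16 T and NK cell, 11 platelet, 10 liver, 9 intestine and 10 skin and muscle genes had a region. The same held for the 16 erythroid, 16 leukocyte, 11 let-7 and 18 tissue microRNA genes. A list of enriched regions does not show whether such transcripts were present without enrichment.

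In a test chosen after the data were seen, genes with a region were compared with neighbouring genes that the table names. These neighbours were overlapped by no region in the annotation, and the GO terms were those in the table. RNA-binding proteins made up 104 of 395 annotated genes with a region (26.3%) against 50 of 382 neighbours (13.1%; odds ratio 2.37, Fisher's exact test over genes, two-sided, Benjamini-Hochberg adjusted over 214 terms, p = 0.00043). By the same Fisher's exact test, the term nucleus was at 55.7% against 39.0% (adjusted p = 0.00043) and protein binding at 69.9% against 55.0% (adjusted p = 0.0016). Cytosol stood at 42.0% against 29.6% (Fisher's exact test, adjusted p = 0.018) and cytoplasm at 43.3% against 31.4% (adjusted p = 0.028). In all, 5 terms were more frequent and 0 less frequent among genes with a region, and 43 terms had an unadjusted p below 0.05. Translation, at 7.85% against 3.14%, did not pass (Fisher's exact test, adjusted p = 0.087). When only the genes overlapped in an exon or UTR were used, 10 terms were more frequent, translation now among them (9.71% against 3.14%, Fisher's exact test, adjusted p = 0.0086), and 2 were less frequent, integral component of plasma membrane (0.971% against 6.81%) and integral component of membrane (13.9% against 24.3%). Neighbours were not matched on expression, which the table does not give, and genes are not independent replicates.

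**Figure D3:**
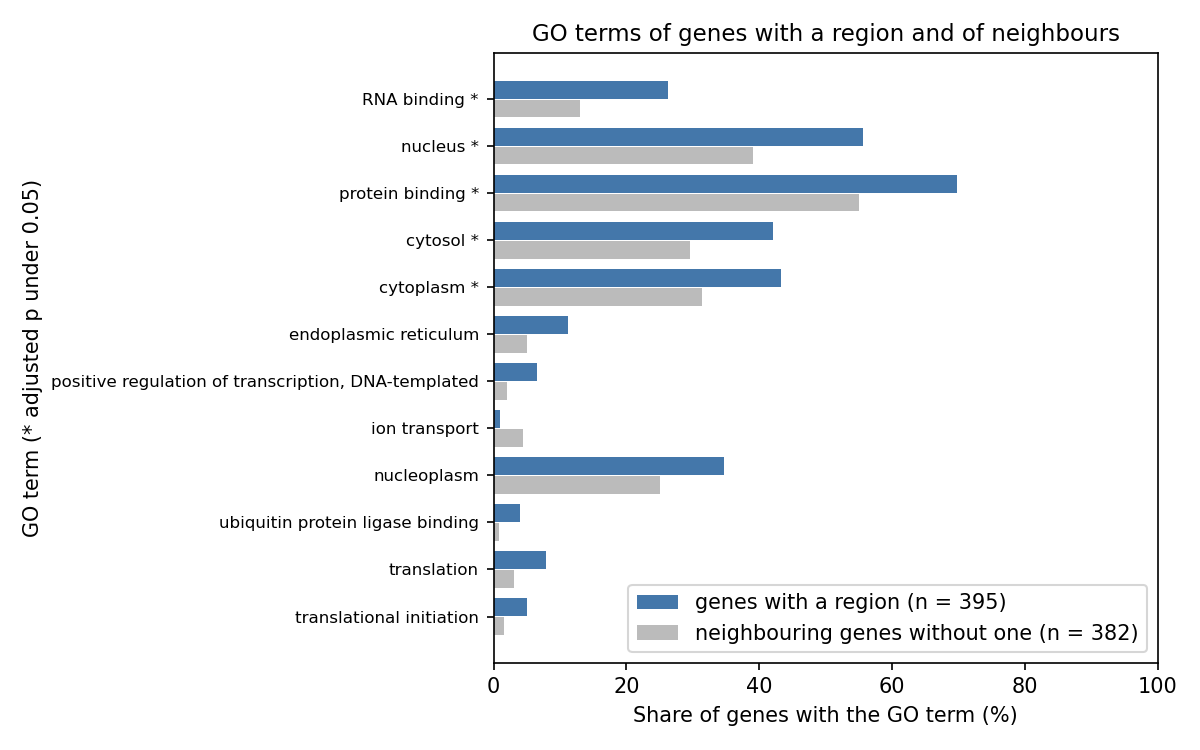
Share of genes (%) carrying each of 12 GO terms with the smallest p, for 395 annotated genes with a region (blue) and 382 neighbouring genes without one (grey); a star marks an adjusted p under 0.05. RNA binding stands at 26.3% against 13.1%.

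The regions had a median length of 179 bases (95% interval 173 to 184, quartiles 148 and 269). The shortest length, 144 bases, was shared by 188 regions (21.1%), so the list has a floor well above the length of a microRNA. Among the autosomes, chromosome 3 held the most regions, 90 or 10.1% (exact 95% binomial interval 8.22 to 12.3), followed by chromosome 1 with 81 and chromosome 8 with 71. Chromosome 22 held 4 and the mitochondrial genome 3. The chromosome 3 interval covers counting error only, and CCDC50 and SMC4 on that chromosome have 9 regions each. Counts were not set against chromosome length or gene number. Sex chromosomes are not reported.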

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

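The alternatives for the GO terms and the pseudogenes, the count by summits and the intron-first order were chosen after seeing the data. The exon and UTR share of 83.5% moved to 72.7% when introns were taken before exons where genes overlap, and stayed within its interval among the 445 (85.4%) and the 89 (80.9%) regions with the highest scores, by summed score (85.5%) and by summits (85.2%). Single classes moved more: the intron share of 8.21% was 19.0% with introns first, and the 3′ UTR share of 14.6% was 5.62% among the 89, 8.02% by summed score and 20.5% by summits. The share with no gene rose from 7.65% to 10.1% among the 89, and the intron share fell to 5.84% among the 445, while the exon share of 66.4% ranged from 57.1% with introns first to 75.2% by summed score. The single microRNA region became 7 with a limit of 1000 bases and 26 with no distance limit, most of them in exons or UTRs of host genes, and was 1 among the 445. The members of the fixed lists fell from 2 to 1 when only exons and UTRs counted, because CSF1R is overlapped in an intron. The 5 GO terms more frequent and 0 less frequent became 10 and 2 with exonic genes only, 9 and 1 with terms of at least 20 genes, and 7 and 0 among the 445; the cause was not tested. The share on chromosome 3 (10.2% without the mitochondrial genome and contigs, 8.96% by summed score), the median length (176 bases among the 445) and the plant families (0 with a species prefix) stayed within their intervals or unchanged. Over the values and their alternatives, 31 stayed and 18 moved. Shares and the median length were judged by their intervals and counts by a ratio of 1.5. By that rule the change from 5 to 7 GO terms counted as staying. The alternatives of fruit and blood overlap, fruit to blood ratios and a minimum of 10 counts were not run, since the table gives no values for them. Sums of peaks per gene were not run because no list had 3 members with a region. No paired analysis was possible because each group has 1 sample and the table could be tied to neither. The depth is unknown and no replicates exist in the labels.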

Other observations

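The tests on the origin of the table and on pseudogenes were chosen after the result was seen. JCHAIN, IRF4, ITGA4, AURKA and VTRNA1-3 were chosen after their values were seen, and were not tested one by one. JCHAIN, which joins polymeric antibodies, had 3 regions with up to 3.28-fold enrichment, in exons 1 and 3 and in the 3′ UTR. IRF4, a transcription factor of plasma cells and activated lymphocytes, had 4.53-fold in an intron, and ITGA4, an integrin of leukocytes, had 3 exonic regions with up to 5.71-fold. Of the B cell list fixed beforehand, 0 of 14 genes had a region. AURKA, a mitotic kinase, had 12.1-fold in exon 3, but the GO term cell division did not pass the test against neighbouring genes, at 4.56% against 2.88% (Fisher's exact test, two-sided, adjusted p = 0.60) and at 5.83% against 2.88% with exonic overlaps (adjusted p = 0.25). Vault RNA VTRNA1-3, a short RNA polymerase III transcript, had a region of 15.1-fold centred just outside the annotated gene.

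The human annotation of a table presented as mouse blood is the observation most in need of a second look. That the coordinates are those of the mouse genome GRCm38 is excluded by the 142 of 889 regions that lie on chromosomes it lacks or past its last annotated base. Whether the table comes from another experiment, or mouse blood reads were aligned to a human genome, stays open. The tag in the peak names is in 0 label fields of the series, which does not separate the 2, and 0 of 59 erythrocyte, neutrophil and blood microRNA genes with a region says nothing in a list of enriched regions alone. That count left out the monocyte list, where 1 of 9 genes, CSF1R, was overlapped in an intron. The B cell, T and NK cell and platelet lists, with 0 overlapped, were also left out.

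Pseudogenes and their parent genes often both held regions. Of 62 pseudogenes with a region, 35 had a parent with one (56.5%, exact 95% interval 43.3 to 69.0), against 7 of 91 neighbouring pseudogenes without a region (7.69%, 3.15 to 15.2; Fisher's exact test over genes, two-sided, odds ratio 15.6, p = 3.2e-11). The share was 30 of 60 with exonic overlaps and 20 of 45 among the regions with the highest scores, and examples are EZH2P1 (5.24-fold) with EZH2 (7.95-fold) and ACTR3P2 (13.9-fold) with ACTR3 (21.1-fold). Reads shared between a pseudogene and its parent may account for this. Transcription of the pseudogenes was not tested, and no biological explanation was. Some pseudogenes share a parent, such as RPL10AP2 and RPL10AP6 with RPL10A, so they are not independent. Neighbours were not matched on the expression of the parent, so the contrast alone does not show shared reads. RPL5P34, RPL5P23 and RPL5P1 had 11.1, 9.41 and 6.46-fold enrichment while no region overlapped RPL5 in the annotation, although a region of 13.5-fold had RPL5 as its closest gene.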
